A study of Mus musculus with 10 samples.

How the data were processed

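RNA expression was measured on Illumina mouse bead arrays in hematopoietic progenitors from the fetal liver of mice that carry a Gata1 allele with reduced expression. The cells had been transduced with the MIGR1 retrovirus, which also encodes green fluorescent protein, carrying ETS2, ERG or FLI1, and RNA came from cells collected at the fourth replating in methylcellulose. The 10 arrays fall into 3 groups by their titles: 2 arrays with ERG (replicates 2 and 3), 4 with ETS2 and 4 with FLI1. The titles abbreviate ETS2 as ETS, and this group was read as ETS2 because the design of the series names ETS2 as the factor. A vector-only arm that the design names was not analysed here, so every comparison is between factors. The labels do not say whether the replicates are separate transductions, cultures or aliquots, so the p-values measure only the spread between these samples.

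The deposited values were expression values per probe on a log2 scale, made by the authors with lumi 1.7.18, per the submitters' processing notes. The log base was read from the range of the values, from 6.938 to 15.429. All 10 arrays held practically 1 distribution, with sorted values that differed between arrays by at most 0.000512, which is the mark of quantile normalization. The transform (plain log2 or variance-stabilizing), the background correction and any probe filter are not given in the sources used here, and no detection p-value was used. The median of all values on the chip, 7.36, served as the level of background. Values near this floor are compressed, so differences of dim genes can be understated. Where the mean of the dimmer group lay at or below this median, the fold is given as a lower bound, counted from the median. No sequencing depth applies to arrays, whose number limits the precision. The median SD within groups was 0.0381 for probes up to the median and 0.0921 for probes with means from 10 to 12.

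Of 24613 probes, 20984 were paired with 1 gene symbol, 1 with several and 3628 with none, and the named probes covered 15967 genes. By Entrez gene identifier, 20968 probes matched the RefSeq gene table of the assembly GRCm38.p6, which gave current symbols and chromosomes. Probes above the median of all values on at least 2 arrays were tested, which kept 13500 probes of 9497 named genes, 1688 of these probes having no symbol. A mean per group was fitted with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with an intensity trend), using all 10 arrays for the estimate of spread. Tests were two-sided, p-values were adjusted by Benjamini-Hochberg within each comparison, and the threshold was 0.05. A second count took absolute log2 differences of at least 1. The moderated F test asked for any difference among the 3 groups. A probe was counted as setting a group apart when both comparisons of that group passed with the same sign.

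The 24 gene lists were fixed before the data were examined, as were the comparisons, the tests and the alternatives. They covered megakaryocyte and platelet, erythroid, mast cell and basophil, neutrophil, monocyte and macrophage, eosinophil, lymphoid, stem and progenitor, endothelial, hepatocyte, and fibroblast and stroma genes. Further lists held the ETS family, GATA1 network factors, cell division, p53 and cell cycle inhibitors, JAK-STAT targets, immediate early genes and MAP kinase feedback, the interferon response, MHC class II, cholesterol synthesis, glycolysis and hypoxia, cytokines and their receptors, sex-linked genes and ribosomal proteins. Each gene was represented by its probe with the highest mean. Lists with at least 5 tested genes, 21 of the 24, were tested with camera at a preset correlation between genes of 0.01, and again with an estimated correlation and with fry. Counts of list members use the adjusted p over all probes, with the count adjusted over the list alone beside it. Named genes followed a fixed rule: the genes of the 3 factors with Gata1 and Gata2, then per comparison the 12 largest rises and 12 largest falls with an absolute log2 difference of at least 1 and no overlap between groups, then up to 4 passing members per list.

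The procedure was tested on simulated data with 13500 probes, of which 50 per size carried a known difference. Each comparison had a single run with 200 changed probes, far fewer than the 1335 to 4683 called in the data. The shares found and the shares of false calls may therefore differ in the data. For FLI1 against ETS2 it found 68% of differences of 0.25 log2 and 100% of those of 0.5 log2 or more, and 6.6% of its calls were false. For ERG against ETS2 it found 58% and 98% at these sizes with 5.82% false calls, and for ERG against FLI1 58% and 96% with 8.76%. A list of 20 genes shifted by 0.3 log2 was found in each comparison and 0 other lists were called. The simulated probes varied independently, so this did not test lists whose genes vary together. In the data the estimated correlation between genes reached 0.643, for cholesterol synthesis.

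Alternatives covered 3 other filters on dim probes, 3 normalizations between arrays, array weights, the variance model without its trend or in its robust form, fits with only the compared groups, the replicate number as a block, averaged probes, and leaving out each array in turn. Unnamed probes took part in the tests and counts but not in the lists. Tables were read with jsonlite 2.0.0, and figures were drawn in Python 3.11.15 with matplotlib 3.10.9, numpy 2.4.6 and pandas 2.3.3.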

Results

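Expression was measured on 10 arrays of mouse fetal liver progenitors with a Gata1 allele of reduced expression, which had been transduced with ETS2 (4 arrays), FLI1 (4 arrays) or ERG (2 arrays), transcription factors of the ETS family. The series asks how these factors act on progenitors that lack normal GATA1 levels, and the comparisons below ask in which genes cells carrying 1 factor differed from cells carrying another. Arrays of 1 group correlated at 0.99647 to 0.99786 over the tested probes (13 pairs), and arrays of different groups at 0.98074 to 0.99251 (32 pairs). ERG and FLI1 arrays were closest across groups (mean r 0.99111), against 0.9843 for ETS2 and FLI1 and 0.98211 for ERG and ETS2. The first principal component, 60.6% of the variance, parted the ETS2 arrays from the others, and the second, 18.9%, parted ERG from FLI1. Among the 13500 tested probes, 5326 (39.5%) differed among the 3 groups by the moderated F test.

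**Figure D1:**
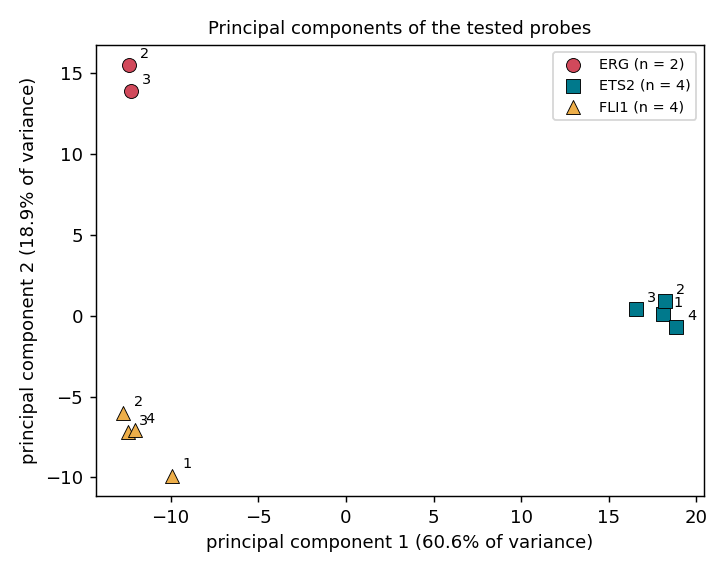
Scores of the 10 arrays on the first and second principal components of the tested probes (60.6% and 18.9% of the variance), by group, with the replicate number beside each point. The 4 ETS2 arrays lie apart from the others along the first axis, and the 2 ERG arrays lie apart from the 4 FLI1 arrays along the second.

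The probes for the genes of the transduced factors differed little between groups. The Ets2 probe had means of 9.02 ± 0.163 (SD, n = 4) with ETS2, 8.90 ± 0.0758 (n = 2) with ERG and 8.77 ± 0.103 (n = 4) with FLI1. The Fli1 probe had means of 10.15 ± 0.0765 (n = 4) with FLI1, 9.87 ± 0.0289 (n = 4) with ETS2 and 9.99 ± 0.0725 (n = 2) with ERG. FLI1 arrays exceeded ETS2 arrays by 0.28 at Fli1 (adjusted p = 0.00137) and were lower by -0.25 at Ets2 (adjusted p = 0.0202), a call that ended without ETS2 replicate 4 (adjusted p = 0.071) or FLI1 replicate 1 (0.0631). The Erg probe lay at background in every group, with means of 7.23 (ERG), 7.25 (ETS2) and 7.21 (FLI1), and was not tested. Whether these probes match the transduced sequences is not known, so they check nothing about the labels. Gata1 had means of 9.15 ± 0.256, 9.12 ± 0.11 and 9.14 ± 0.166 with ERG, ETS2 and FLI1, and Gata2, a factor of early progenitors and mast cells, had 14.64, 14.78 and 14.68. No difference of Gata1 or Gata2 passed the threshold with all arrays. Without ETS2 replicate 2, Gata2 was lower with ERG (-0.19, adjusted p = 0.0354) and with FLI1 (-0.15, adjusted p = 0.0338) than with ETS2.

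Several mast cell and basophil genes had probes far above background in all 3 groups. Cpa3, a mast cell carboxypeptidase, had means of 14.60, 14.55 and 14.54 with ERG, ETS2 and FLI1. Prss34, a basophil and mast cell protease, had 13.43, 13.42 and 13.59, and Srgn, the proteoglycan core of secretory granules, had 13.71, 13.68 and 13.75. Others on this list were nearer to background, such as the cytokine gene Il4 with 7.52, 7.62 and 7.36 and the protease gene Mcpt4 with 7.67, 8.09 and 8.04, and 3 of its 20 genes with a probe were too dim to test. Intensities of different probes do not compare amounts of different RNAs.

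FLI1 was first compared with ETS2. Igf2, a fetal growth factor, was 23.5-fold higher with FLI1, with means of 12.47 ± 0.0894 against 7.92 ± 0.134 (SD, n = 4 each), a log2 difference of 4.56 (SE 0.0719, adjusted p = 1.7e-16). Hba-a1, an alpha globin gene, was 25.7-fold lower with FLI1 at 8.40 ± 0.461 against 13.08 ± 0.353 (n = 4 each, adjusted p = 5.35e-10). Gpnmb, a macrophage glycoprotein, Pf4, platelet factor 4, and Il1b, an inflammatory cytokine, were also lower with FLI1, while Hmgcs1, an enzyme of cholesterol synthesis, and Cdkn2a, which encodes inhibitors of cell division, were higher. In all, 2583 probes were higher and 2100 lower (4683, 34.7%), of which 20 and 102 differed by at least 1 log2 unit. The majority turned under cyclic loess, with 2182 higher and 2388 lower. The median absolute difference of the called probes was 0.259.

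Of 11 tested monocyte and macrophage genes, 8 were lower with FLI1 than with ETS2 and 0 higher (8 and 0 adjusted over the list alone, camera adjusted p = 0.000508, or adjusted p = 0.172 with an estimated correlation). Clec4n, which encodes a receptor for fungal sugars, was 4.97-fold lower, Lyz2, a lysozyme gene, 3.34-fold, and Ctss, a lysosomal protease gene, 1.8-fold. Outside the list, Gpnmb was 4.48-fold lower at 11.93 ± 0.41 against 14.09 ± 0.249 (n = 4 each). Mmp12, macrophage elastase, was 5.28-fold lower at 9.61 ± 0.42 against 12.01 ± 0.345 (n = 4 each). Lpl, lipoprotein lipase, was 4.76-fold lower. The survival genes Bcl2a1b and Bcl2a1a were 6.59-fold and 3.98-fold lower, and Fez1 was 4.98-fold lower.

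Of 12 tested erythroid genes, 7 were lower with FLI1 and 0 higher (7 and 0 adjusted over the list alone, camera adjusted p = 0.000508, or adjusted p = 0.185 with an estimated correlation). Beside Hba-a1, Slc4a1, the anion exchanger of red cells, was at least 3.22-fold lower, Tfrc, the transferrin receptor, 1.97-fold, and Alas2, the first enzyme of heme synthesis in red cells, at least 1.83-fold. Of 21 megakaryocyte and platelet genes, 10 were lower and 1 higher (11 and 1 adjusted over the list alone, camera adjusted p = 0.000555, or adjusted p = 0.172 with an estimated correlation). Pf4 was 6.69-fold lower at 7.62 ± 0.117 against 10.36 ± 0.655 (n = 4 each, adjusted p = 8.05e-08). Treml1, a receptor of platelet granules, was at least 2.2-fold lower, and F2rl2, a thrombin receptor, 1.66-fold. The list's other markers did not all move: Itga2b had means of 10.61 and 10.75 (adjusted p = 0.361), and Gp5 had 10.41 and 10.47 (adjusted p = 0.707).

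Cytokines and their receptors were lower with FLI1 in 11 of 24 genes and higher in 3 (11 and 3 adjusted over the list alone, camera adjusted p = 0.00216, or adjusted p = 0.172 with an estimated correlation), among them Il1b (4.54-fold lower), Ccl2 (2.46-fold) and Csf2ra (2.14-fold). Immediate early genes and feedback genes of the MAP kinase pathway were lower in 7 of 17 and higher in 1 (10 and 1 adjusted over the list alone, camera adjusted p = 0.00129, or adjusted p = 0.31 with an estimated correlation). Dusp4 and Dusp6, MAP kinase phosphatases, were 2.92-fold and 2.58-fold lower, and Egr1 was 3.53-fold lower with ETS2 arrays that spread widely (11.01 ± 1.16, n = 4). MHC class II genes were lower in 3 of 6 (4 adjusted over the list alone) and higher in 0 (camera adjusted p = 0.0036, or adjusted p = 0.172 with an estimated correlation), Cd74, the class II chaperone, by 2.62-fold. H2-Ab1, the gene of a class II chain, lay near background with FLI1 and ETS2 (means 7.32 and 7.38) and did not pass (limma adjusted p = 0.315). Mast cell and basophil genes were lower in 5 of 17 and higher in 2 (5 and 2 adjusted over the list alone, camera adjusted p = 0.0438, or adjusted p = 0.172 with an estimated correlation). The largest of these were the tryptases Tpsab1 (at least 6.04-fold lower) and Tpsb2 (3.81-fold lower), and Fcer1a, a chain of the IgE receptor, was 1.85-fold lower.

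Cholesterol synthesis genes were higher with FLI1 in 9 of 15 and lower in 0 (9 and 0 adjusted over the list alone, camera adjusted p = 0.00436, or adjusted p = 0.445 with an estimated correlation), including Msmo1 (1.57-fold) and Hmgcs1 (1.56-fold). Of 16 genes of the p53 and cell cycle inhibitor list, 11 were higher and 2 lower (11 and 2 adjusted over the list alone, camera adjusted p = 0.00708, or adjusted p = 0.22 with an estimated correlation). Cdkn2a was 1.75-fold higher, Ccng1 1.51-fold and Bbc3, a cell death gene, 1.5-fold. Other genes higher with FLI1 were Fam155a (at least 5.19-fold) and Clec4g (at least 2.54-fold), both with ETS2 means at background, Cxcr2, a chemokine receptor of neutrophils (2.48-fold), Il16 (2.45-fold), Otop1 (2.43-fold), Ddit4 (2.35-fold), Depdc1b (2.29-fold), Glcci1 (2.23-fold), Ctsg (2.23-fold), Tob1 (2.19-fold) and H2ac18 (2.15-fold). Averaging the probes of a gene moved Glcci1 to 0.44 log2 from 1.16, Cdkn2a to 0.43 from 0.81, Dusp6 to -0.84 from -1.37 and Cbfa2t3 to 0.41 from 0.79. The other tested probes of these genes had means no higher than 7.73, near background, where differences are compressed. Eif2s3y and Kdm5d, genes of the Y chromosome, lay at background on all 4 FLI1 arrays, with means of 7.29 ± 0.00914 and 7.21 ± 0.0194 (n = 4). They were at least 6.21-fold and 1.61-fold lower than with ETS2, where the means were 9.99 ± 0.169 and 8.04 ± 0.0427 (n = 4).

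The other 12 tested lists did not pass for FLI1 against ETS2, in counts of higher and lower genes followed by those adjusted over the list alone. Neutrophil genes were higher in 3 and lower in 7 of 17 (4 and 8), with S100a9 and S100a8 3.73-fold and 3.81-fold lower and Lcn2 2.22-fold lower. Glycolysis and hypoxia genes were higher in 4 and lower in 5 of 16 (4 and 6), JAK-STAT targets in 2 and 7 of 17 (2 and 7), GATA1 network factors in 5 and 4 of 17 (6 and 4) and stem and progenitor genes in 5 and 3 of 15 (6 and 3). Nfe2, a factor of red cells and platelets, was 1.76-fold higher with FLI1 and Cbfa2t3, a corepressor, 1.73-fold. Cell division genes were higher in 6 and lower in 1 of 20 (6 and 1), ribosomal proteins in 7 and 1 of 16 (7 and 2), lymphoid genes in 2 and 3 of 7 (2 and 3) and interferon response genes in 0 and 2 of 10 (0 and 2). ETS family genes were higher in 2 and lower in 3 of 13 (2 and 3), endothelial genes in 1 and 1 of 8 (1 and 0) and hepatocyte genes in 0 and 1 of 6 (0 and 1). The ETS family had a median of -0.00183 against a mean of 0.00064, with camera down and fry up. The untested lists gave 1 higher and 0 lower of 3 eosinophil genes (1 and 0), 1 and 2 of 3 fibroblast and stroma genes (1 and 2) and 0 and 2 of 3 sex-linked genes (0 and 2).

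ERG was compared with ETS2 in the same way. Igf2 was 20.3-fold higher with ERG, at 12.26 ± 0.0474 (SD, n = 2) against 7.92 ± 0.134 (n = 4), a log2 difference of 4.34 (SE 0.088, adjusted p = 1.72e-14). Gpnmb was 30.6-fold lower with ERG, at 9.16 ± 0.183 (n = 2) against 14.09 ± 0.249 (n = 4, adjusted p = 4.38e-11), though its log2 difference moved from -4.94 to -2.81 when its 4 probes were averaged. Mmp12, macrophage elastase, and Tpsb2, a mast cell tryptase, were lower with ERG, and Msmo1, an enzyme of cholesterol synthesis, and Mcm5, a part of the replicative helicase, were higher. In all, 1988 probes were higher with ERG and 1762 lower (3750, 27.8%), of which 38 and 122 differed by at least 1 log2 unit. Under cyclic loess 1675 were higher and 1989 lower, which turned the majority. The count was 2471 without ERG replicate 2 and 2496 without ERG replicate 3.

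Monocyte and macrophage genes were lower with ERG in 8 of 11 and higher in 1, Adgre1 (9 and 1 adjusted over the list alone, camera adjusted p = 2.97e-05, or adjusted p = 0.267 with an estimated correlation). Clec4n was 9.64-fold lower, Lyz2 7.96-fold and Ctss at least 2.29-fold. Mmp12 was 19.9-fold lower at 7.69 ± 0.0121 (n = 2) against 12.01 ± 0.345 (n = 4), and Lpl was 9.74-fold lower. Bcl2a1b and Bcl2a1a were 11.6-fold and 5.31-fold lower. Ifi27, an interferon-inducible gene, was 6.39-fold lower and Ddc, the enzyme that makes dopamine and serotonin, 4.74-fold. Mast cell and basophil genes were lower in 7 of 17 and higher in 2 (7 and 2 adjusted over the list alone, camera adjusted p = 0.0394, or adjusted p = 0.267 with an estimated correlation). Tpsb2 was lower by a log2 difference of -3.32 (SE 0.0902, adjusted p = 5.3e-13), Tpsab1 5.27-fold and Cma1, a chymase, 2.11-fold. In the other direction Mcpt8, a basophil protease, was 2.25-fold higher with ERG.

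Cytokines and their receptors were lower with ERG in 9 of 24 and higher in 2 (10 and 3 adjusted over the list alone, camera adjusted p = 0.0409, or adjusted p = 0.267 with an estimated correlation), Il1b by 4.06-fold and Csf2ra by 2.9-fold. Immediate early and MAP kinase feedback genes were lower in 8 of 17 and higher in 2 (8 and 2 adjusted over the list alone, camera adjusted p = 0.00332, or adjusted p = 0.429 with an estimated correlation), with Egr1 7.15-fold, Dusp4 2.82-fold and Dusp6 2.23-fold lower. Dusp6 moved to -0.70 log2 from -1.15 when averaged with a second probe near background. Cholesterol synthesis genes were higher in 13 of 15 and lower in 0 (14 and 0 adjusted over the list alone, camera adjusted p = 2.12e-06, or adjusted p = 0.402 with an estimated correlation). Msmo1 was 2.02-fold higher, Stard4, a cholesterol carrier, 1.96-fold and Hmgcs1 1.87-fold. Cell division genes were higher in 7 of 20 and lower in 1 (7 and 1 adjusted over the list alone, camera adjusted p = 0.00718, or adjusted p = 0.535 with an estimated correlation). The largest rises on this list were in Mcm5 (2.29-fold), Mcm7 (1.68-fold) and Mcm4 (1.55-fold), which encode parts of the replicative helicase, while Mcm6 (0.33 log2, adjusted p = 0.109) and the mitotic kinase gene Plk1 (means 8.78 and 8.70, adjusted p = 0.702) did not pass.

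Other genes higher with ERG were 2210407C18Rik (4.56-fold), Clec4g (at least 3.7-fold), Runx1t1, a corepressor (3.73-fold), Stfa2, a stefin protease inhibitor (3.23-fold), Cstdc5 (3.23-fold), Pglyrp1 (2.95-fold), Ly6c1 (2.88-fold), Fam155a (at least 2.76-fold), Depdc1b (2.72-fold), Ebi3, a cytokine subunit (2.57-fold), and Tek, the angiopoietin receptor (2.53-fold). Runx1t1 fell to 0.99 log2 from 1.90 when averaged with a second probe near background. Cdkn2a was 2.1-fold higher and Nfe2 2.01-fold. Averaging with a second probe near background also moved Cdkn2a to 0.57 log2 from 1.07 and Mcm4 to 0.41 from 0.63.

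The remaining 15 tested lists did not pass for ERG against ETS2, with counts of higher and lower genes followed by those adjusted over the list alone. Erythroid genes were higher in 1 and lower in 5 of 12 (1 and 6, camera adjusted p = 0.0573). Hba-a1 was 1.94-fold lower with ERG, at 12.13 ± 0.737 (n = 2) against 13.08 ± 0.353 (n = 4), a log2 difference of -0.96 that became -0.43 without ERG replicate 3 (adjusted p = 0.396) and -1.48 without ERG replicate 2 (adjusted p = 0.00437). Its call also ended with the robust variance model (adjusted p = 0.123). Megakaryocyte and platelet genes were higher in 5 and lower in 5 of 21 (7 and 5), with Itgb3, a platelet integrin, 1.33-fold higher and Tbxas1, thromboxane synthase, 1.55-fold lower. MHC class II genes were higher in 2 and lower in 4 of 6 (2 and 4), p53 and cell cycle inhibitors in 7 and 2 of 16 (9 and 2), ribosomal proteins in 7 and 1 of 16 (8 and 1), JAK-STAT targets in 3 and 5 of 17 (4 and 6) and stem and progenitor genes in 4 and 3 of 15 (5 and 5). Neutrophil genes were higher in 4 and lower in 1 of 17 (4 and 1), GATA1 network factors in 3 and 2 of 17 (3 and 2), glycolysis and hypoxia genes in 3 and 3 of 16 (3 and 3), and ETS family genes in 1 and 1 of 13 (0 and 1). Endothelial genes were higher in 2 and lower in 2 of 8 (2 and 2), hepatocyte genes in 2 and 0 of 6 (2 and 0), interferon response genes in 1 and 3 of 10 (1 and 3), and lymphoid genes in 0 and 3 of 7 (0 and 3). Median and mean differed in sign for neutrophil (-0.0542 and 0.0392, camera up), interferon response (0.0281 and -0.0519, camera down), endothelial (-0.00261 and 0.15, camera up), glycolysis and hypoxia genes (0.00126 and -0.00673, camera down), and the untested fibroblast and stroma genes (0.0351 and -0.12). The untested lists gave 0 higher and 0 lower of 3 eosinophil genes (0 and 0), 0 and 1 of 3 fibroblast and stroma genes (0 and 1) and 0 and 2 of 3 sex-linked genes (0 and 2).

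**Figure D2:**
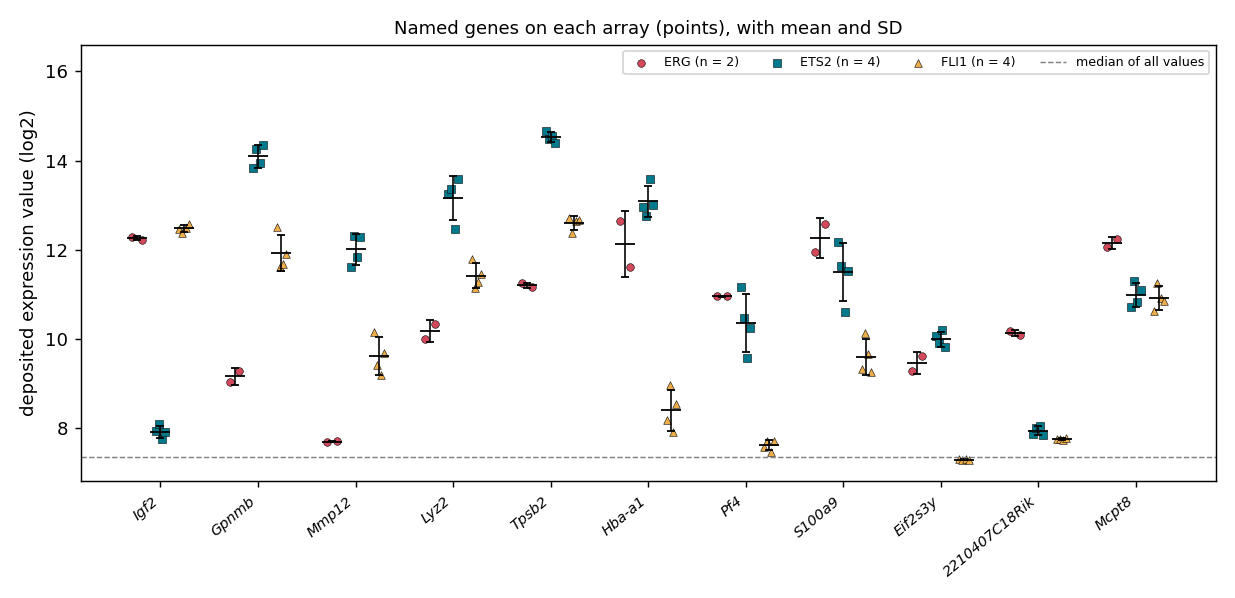
Deposited expression (log2) of selected genes on each array, with points for the arrays, horizontal marks for group means and bars for the SD, and a dashed line at the median of all values. Igf2 lies between 7.75 and 8.08 on the 4 ETS2 arrays and above 12 on all others.

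ERG and FLI1 were the most alike of the groups. Hba-a1 was 13.2-fold higher with ERG, at 12.13 ± 0.737 (SD, n = 2) against 8.40 ± 0.461 (n = 4, adjusted p = 3.56e-07). Pf4 was 10.1-fold higher, at 10.955 ± 0.00697 (n = 2) against 7.62 ± 0.117 (n = 4, adjusted p = 4.78e-07). S100a9, a calcium-binding protein of neutrophils, was higher with ERG, and Gpnmb was lower. In all, 677 probes were higher with ERG and 658 lower (1335, 9.889%), of which 36 and 15 differed by at least 1 log2 unit. The majority turned in some alternatives, such as the filter at the 75th percentile (524 higher and 573 lower) and averaged probes (536 and 552). The count was 595 without ERG replicate 2 and 782 without ERG replicate 3, and of 81 gene differences named for this comparison, 30 lost their call when 1 ERG array was left out.

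Megakaryocyte and platelet genes were higher with ERG in 11 of 21 and lower in 2 (11 and 2 adjusted over the list alone, camera adjusted p = 1.03e-05, or adjusted p = 0.322 with an estimated correlation). Besides Pf4, Treml1 was at least 2.77-fold higher, F2rl2 1.9-fold and Cd226 1.57-fold, while Tbxas1 and Vwf, the von Willebrand factor gene, were the lower members. Erythroid genes were higher in 4 of 12 and lower in 0 (6 and 0 adjusted over the list alone, camera adjusted p = 0.00584, or adjusted p = 0.596 with an estimated correlation). Beside Hba-a1 these were Car2, a carbonic anhydrase (1.68-fold), Slc4a1 (at least 1.69-fold) and Alas2 (at least 1.35-fold). The call of Slc4a1 ended without ERG replicate 2 (0.50 log2 from 0.79, adjusted p = 0.423), without any 1 of the FLI1 arrays (adjusted p from 0.056 to 0.0708), with the replicate number as a fixed block (0.156), without the intensity trend (0.0891) and with the robust variance model (0.201). The call of Alas2 ended without ERG replicate 2 (0.33 log2 from 0.52, adjusted p = 0.267) and with the robust variance model (0.0617). Neutrophil genes were higher in 4 of 17 and lower in 1 (4 and 2 adjusted over the list alone, camera adjusted p = 0.031, or adjusted p = 0.596 with an estimated correlation). S100a9 was 6.36-fold higher at 12.26 ± 0.457 (n = 2) against 9.59 ± 0.397 (n = 4), and Lcn2, an iron-trapping protein of neutrophils, was 2.79-fold higher. S100a8 was 3.14-fold higher, and its call ended without ERG replicate 3 (1.30 log2 from 1.65, adjusted p = 0.121) and with the robust variance model (adjusted p = 0.0963). The lower member was Ctsg, which was 1.52-fold lower, and its call ended without ERG replicate 2 (-0.52 log2 from -0.61, adjusted p = 0.0827).

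Cholesterol synthesis genes were higher with ERG in 4 of 15 and lower in 0 (6 and 0 adjusted over the list alone, camera adjusted p = 0.000188, or adjusted p = 0.61 with an estimated correlation), with Nsdhl 1.51-fold and Hsd17b7 1.4-fold higher. The call of Hsd17b7 ended without ERG replicate 2 (0.41 log2 from 0.49, adjusted p = 0.0827). Stard4 (1.36-fold) lost its call without ERG replicate 2 (0.36 log2 from 0.44, adjusted p = 0.246), ERG replicate 3 (0.53, 0.0571) or FLI1 replicate 1 (0.36, 0.051). Cyp51 (1.44-fold, adjusted p = 0.0474) lost its call in 11 alternatives, with an adjusted p from 0.0504 without ETS2 replicate 2 to 0.385 without ERG replicate 2 (0.39 log2 from 0.52). Cell division genes were higher in 3 of 20 and lower in 0 (3 and 0 adjusted over the list alone, camera adjusted p = 0.0183, or adjusted p = 0.662 with an estimated correlation). These were Mcm2 (1.42-fold), Mcm5 (1.52-fold) and Mcm7 (1.34-fold), while Mcm4 (0.21 log2, adjusted p = 0.186) and Mcm6 (0.0562 log2, adjusted p = 0.879) did not pass. The call of Mcm5 ended without ERG replicate 2 (0.59 log2 from 0.60, adjusted p = 0.102) or ERG replicate 3 (0.62, adjusted p = 0.0775). The call of Mcm7 ended without ERG replicate 2 (0.46 log2 from 0.42, adjusted p = 0.127), ERG replicate 3 (0.39, 0.187), FLI1 replicate 1 (0.34, 0.0645) or FLI1 replicate 3 (0.40, 0.0669), and with the replicate number as a fixed block (0.32, 0.0768).

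Other genes higher with ERG were 2210407C18Rik (5.2-fold), Stfa2 (5.11-fold), Slpi, a protease inhibitor (3.96-fold), Ccl2, a monocyte chemokine (3.48-fold), Cstdc5 (3.43-fold), Amigo2 (2.94-fold) and Eif2s3y (at least 4.28-fold). Genes lower with ERG were Gpnmb (6.83-fold, with a log2 difference that moved from -2.77 to -1.19 when its probes were averaged), Mmp12 (3.78-fold), Cytip (3.01-fold), 4933416I08Rik (2.96-fold), Otop1 (2.68-fold), Tpsb2 (2.63-fold), Kcnn4, a potassium channel (2.21-fold), and Casp1, the protease that activates Il1b (2.06-fold). Without ERG replicate 2, calls ended for Lyz2 (2.38-fold lower, -1.08 log2 from -1.25, adjusted p = 0.0598), Lpl (2.05-fold lower, -0.96 from -1.03, adjusted p = 0.0672) and Mrgprb2, a mast cell receptor (2.47-fold lower, -1.23 from -1.31, adjusted p = 0.0933). That of Mrgprb2 also ended with the robust variance model (adjusted p = 0.0945). Ammecr1l was 2.51-fold lower with ERG, but ERG replicate 2 alone held this call, and without it the log2 difference was -0.29 (adjusted p = 0.413), against -2.37 without ERG replicate 3. The call also ended without the intensity trend (adjusted p = 0.0606) and with the robust variance model (0.166).

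The other 16 tested lists did not pass for ERG against FLI1, with counts of higher and lower genes followed by those adjusted over the list alone. Macrophage genes were higher in 0 and lower in 4 of 11 (0 and 5), mast cell and basophil genes in 3 and 4 of 17 (4 and 4), cytokines and their receptors in 4 and 4 of 24 (6 and 5) and glycolysis and hypoxia genes in 4 and 1 of 16 (4 and 3). Mcpt8 was 2.36-fold higher with ERG, Hdc, the enzyme that makes histamine, 1.68-fold higher, and Cma1 1.87-fold lower. JAK-STAT targets were higher in 3 and lower in 1 of 17 (4 and 3), immediate early and MAP kinase feedback genes in 2 and 2 of 17 (2 and 2), p53 and cell cycle inhibitors in 1 and 2 of 16 (3 and 3) and stem and progenitor genes in 1 and 2 of 15 (2 and 3). Endothelial genes were higher in 2 and lower in 1 of 8 (3 and 2), with Tek 2.1-fold higher, MHC class II genes in 2 and 1 of 6 (2 and 2), GATA1 network factors in 1 and 1 of 17 (1 and 2) and lymphoid genes in 1 and 1 of 7 (2 and 1). Hepatocyte genes were higher in 1 and lower in 0 of 6 (1 and 0), interferon response genes in 1 and 0 of 10 (1 and 0), ribosomal proteins in 1 and 0 of 16 (1 and 0), and ETS family genes in 0 and 0 of 13 (0 and 0). Signs of median, mean and camera differed for 6 lists. Median and mean were -0.000275 and 0.0785 for lymphoid genes (camera down), 0.00802 and -0.00358 for stem and progenitor genes (down, but fry up), and 0.0345 and -0.0037 for JAK-STAT targets (up). They were 0.00283 and -0.0173 for immediate early genes (up), -0.0938 and 0.0313 for MHC class II (up) and -0.0106 and 0.0833 for cytokines (up). The untested lists gave 0 higher and 1 lower of 3 eosinophil genes (0 and 1), 1 and 1 of 3 fibroblast and stroma genes (2 and 1) and 2 and 0 of 3 sex-linked genes (2 and 0).

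**Figure D3:**
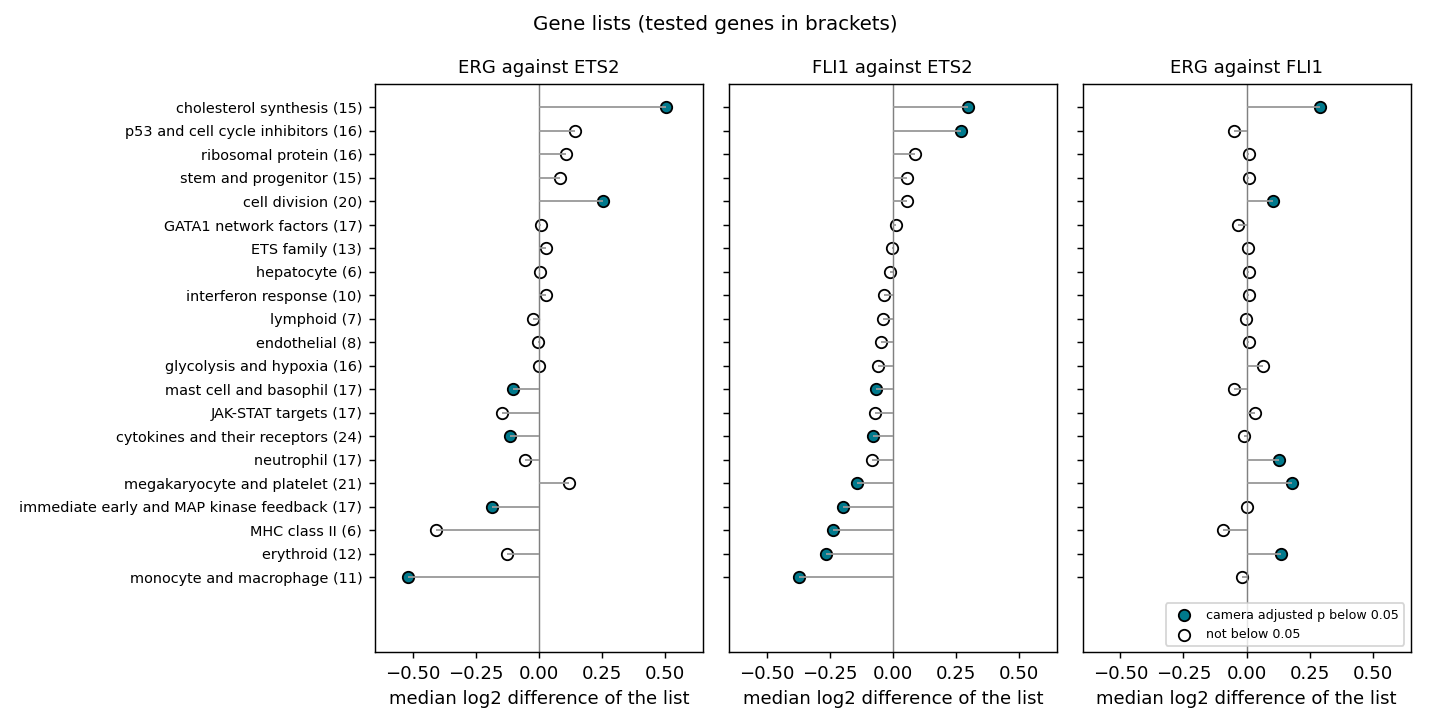
Median log2 difference of the tested genes of each list in the 3 comparisons, with filled points where the camera adjusted p at a preset correlation lay below 0.05. Filled points number 6 for ERG against ETS2, 9 for FLI1 against ETS2 and 5 for ERG against FLI1. With an estimated correlation none passed, and the lowest adjusted p was 0.267, 0.172 and 0.322.

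Genes that set 1 factor apart from both others were most frequent for ETS2, with 1298 probes higher and 1290 lower than in both other groups, or 1481 and 1047 under cyclic loess. ERG had 373 higher and 330 lower, and FLI1 301 higher and 309 lower. Independent lists of these sizes would share 274 and 380 probes for ETS2, 99.7 and 85.9 for ERG and 126 and 105 for FLI1. In 50 simulations of unchanged groups that kept the shared arrays, the mean count was 0 for ETS2 and FLI1 and 0.12 for ERG. These simulations held no difference in either comparison, so they do not measure the overlap that shared arrays add to real differences. Splitting the 4 arrays of the group between both comparisons, over 6 splits, gave on average 977 higher and 793 lower for ETS2 and 171 and 201 for FLI1. Each comparison then held only 2 arrays of the group. Fewer arrays as well as the absence of shared arrays can lower these counts, and the splits do not part the 2. ERG, with 2 arrays, was not split. With ETS2 alone, Mmp12 and Tpsab1 were higher and Igf2 lower than with both other factors. With FLI1 alone, Hba-a1, Pf4 and S100a9 were lower, and with ERG alone 2210407C18Rik and Mcpt8 were higher. ERG's count fell to 327 without ERG replicate 2 and 429 without ERG replicate 3, and FLI1's to 303 and 373.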

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

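Single arrays were compared with the other 3 of their group for the 170 named genes in the ETS2 and FLI1 groups, 340 sets of 4 arrays, and no test here was chosen after its result was seen. In 19 sets 1 array stood farther from its nearest neighbour, relative to the range, than Dixon's critical value allows, where chance alone gives about 1 in 20, or 17. No explanation was tested for any of them.

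ETS2 replicate 3 was apart for S100a8 (11.45, others 12.94 to 12.99), Slc4a1 (9.839, others 8.738 to 8.845), Mrgprb2 (9.597, others 10.70 to 10.87) and Ifi47 (7.51, others 7.677 to 7.701). FLI1 replicate 1 was high for Blnk (7.816, others 7.56 to 7.571), Ctss (7.951, others 7.597 to 7.635) and Mef2c (7.63, others 7.555 to 7.567). The same array was low for Amigo2 (9.748, others 9.872 to 9.887) and Cdkn2b (10.35, others 10.67 to 10.71). ETS2 replicate 1 was apart for Cdkn2b (9.899, others 10.31 to 10.37), Ier3 (14.37, others 14.11 to 14.14) and Kdm5d (8.107, others 8.018 to 8.028). ETS2 replicate 4 was apart for Cd3g (7.503, others 7.376 to 7.392), Mafg (10.65, others 10.54 to 10.55), Pdgfrb (7.552, others 7.463 to 7.478) and Rpl7 (14.15, others 14.24 to 14.25). ETS2 replicate 2 was high for H2-Ab1 (7.532, others 7.327 to 7.341). FLI1 replicate 2 was high for Etv6 (8.548, others 8.393 to 8.407) and low for Pim2 (7.887, others 8.184 to 8.188).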

How the results depend on the processing

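All alternatives were fixed in advance and no test here was chosen after its result was seen. Of 285 named gene differences 275 passed, 221 of these passed in every alternative that gave a value, 54 lost their call in at least 1, and 0 of the 275 reversed. Probe counts stayed within 1.5 times their main value under every filter, normalization, variance model, array weighting, block and averaging alternative. Under cyclic loess the split for ERG against ETS2 went from more probes higher (1988 and 1762) to more lower (1675 and 1989), for FLI1 against ETS2 from 2583 and 2100 to 2182 and 2388, probes setting ETS2 apart went from 1298 and 1290 to 1481 and 1047, and its lists for ERG against ETS2 went from 2 up and 4 down to 3 up and 2 down; the cause was not tested. Normalizing by quantiles again and shifting to a common median moved nothing, so both say nothing about stability. Leaving out 1 array at a time gave ranges of 2471 to 3821 probes for ERG against ETS2, 4063 to 4619 for FLI1 against ETS2, 595 to 1354 for ERG against FLI1 and 4662 to 5123 in the F test. Probes set apart ranged from 327 to 718 for ERG, 1789 to 2554 for ETS2 and 303 to 600 for FLI1, and lists past the threshold from 5 to 7, 8 to 11 and 3 to 6 in the order of the comparisons above. The lowest values came without an ERG array, where fewer samples were left and the lone ERG array was assumed to vary like the other groups, except for FLI1 against ETS2 (without FLI1 replicate 3) and the lists of ERG against ETS2 (without ETS2 replicate 2) and ERG against FLI1 (3 without FLI1 replicate 1). With the filter at the 75th percentile, 3 lists passed for ERG against ETS2 and 5 for FLI1 against ETS2, with fewer genes tested. With camera's estimated correlation 0 lists passed in any comparison (3, 5 and 1 at an unadjusted p under 0.05), and fry called 14, 17 and 6. The mean correlation within groups was 0.9975 without a filter and 0.9869 as Spearman's, against 0.99695. Replicate numbers did not pair the samples (consensus correlation -0.0447), and with the replicate block as a fixed term the counts were 3060, 4523 and 941, as a random term 3677, 4541 and 1285. Values that did not pass and reversed were Gata1 for ERG against ETS2 (-0.0127 under cyclic loess, -0.0267 without ETS2 replicate 4, leave-one-out range -0.16 without ERG replicate 2 to 0.20 without ERG replicate 3), for FLI1 against ETS2 (-0.014 under cyclic loess, -0.0333 without ETS2 replicate 4, range -0.0564 without FLI1 replicate 4 to 0.0788 without FLI1 replicate 2) and for ERG against FLI1 (-0.0579 without FLI1 replicate 2, range -0.17 without ERG replicate 2 to 0.19 without ERG replicate 3), and Gata2 for ERG against FLI1 (range -0.0929 without ERG replicate 3 to 0.0237 without ERG replicate 2); the cause was not tested. Gata2 gained a call without ETS2 replicate 2 for ERG against ETS2 (-0.19, adjusted p = 0.0354) and FLI1 against ETS2 (-0.15, adjusted p = 0.0338).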

Other observations

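The tests on macrophages, and the X chromosome values for ERG and for 1 probe per gene, were chosen only after the results were seen. So were the genes of the next 2 paragraphs. The remaining tests were written before their results, but the Igf2 and Y-linked patterns they ask about had been seen.

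Several genes moved between arrays of 1 group. Fbxw5 was at 10.34 on ETS2 replicate 3 and 10.51 on FLI1 replicate 3 and between 7.44 and 7.98 on the other 8 arrays. Rbm3, a cold-inducible RNA-binding protein, was at 9.07 on ETS2 replicate 3 and 8.996, 9.24 and 8.72 on FLI1 replicates 1 to 3, and at or below 7.46 on the others. Pcyt1b on ETS2 replicate 2 and Ammecr1l on ERG replicate 2 lay at 6.938, the lowest value of the chip. Egr1 ranged from 9.67 to 12.31 within ETS2. ETS2 replicate 3 had the highest Hba-a1 of its group (13.585) with the lowest Pf4 (9.58), S100a9 (10.61) and Lyz2 (12.45).

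Among genes listed as imprinted, Tspan32 and Cd81 did not follow Igf2. Tspan32 was highest with ERG (11.21, against 10.28 with ETS2 and 10.04 with FLI1). Cd81 was at 13.04 with ERG, 12.47 with ETS2 and 11.49 with FLI1. Impact was highest with ETS2 (10.42, against 10.07 with ERG and 9.97 with FLI1), as was Cdkn1c (7.90, against 7.29 and 7.51).

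Igf2 was lower with ETS2 than with both other factors, and a general fall of imprinted genes in ETS2 cells could be a candidate explanation. Of 29 listed imprinted genes other than Igf2, only 11 were tested, and these 11 showed no general fall. The listed genes that were not tested had no probe or were too dim, so nothing is known of them. Their median in ETS2 minus the mean of both other groups was 0.17 (SE 0.104), with 0 lower and 3 higher than in both. Of these genes, Dlk1, Rtl1, Ndn and Kcnq1 lay near background in every group, so they could hardly have fallen. The genes were not divided by the parental copy expressed, so a change of imprinting itself was not tested. A fall of genes of the fetal stage stays open, since of 12 such genes only 3 were tested, with a median of -0.0087, 0 lower and 1 higher than in both, Igf2bp3 (0.33, adjusted p = 0.0224 and 5.15e-05). Igf2 has 1 probe on this chip, so no second probe bears on it, and an effect of ETS2 itself was not tested apart from the group.

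Eif2s3y and Kdm5d were at background on all 4 FLI1 arrays. With ERG their means were 9.45 and 7.59, below those of 9.99 and 8.04 with ETS2. Of 3 tested sex-linked genes, 2 were lower with ERG than with ETS2 and 0 higher. The Y-linked signal thus differed among all 3 groups, and a difference in the source of the cells is not excluded for ERG against ETS2. The FLI1 cells may have come from a female embryo, in which case the comparisons with FLI1 cannot tell the factor from the source of the cells. Genes that escape X inactivation would then be higher in the FLI1 cells. The median of 6 such genes was 0.183 (SE 0.111) higher than with ETS2 but only 0.0396 (SE 0.0821) higher than with ERG. Of these, 1, Utp14a, was higher than in both, while Pbdc1 was lower than with ERG (-0.28 log2, limma adjusted p = 0.0159). The values thus do not decide, and a loss of the Y chromosome in culture was not tested. Calls between FLI1 and ETS2 were not concentrated on the X chromosome. There 38.1% of the 354 tested probes were called, against 35.1% of autosomal probes. The odds ratio was 1.14 with an upper confidence bound of 1.422, below the 1.5 set beforehand (Fisher's exact p = 0.258). This compares frequencies of calls only and was no test of the source of the cells. For ERG against FLI1 the odds ratio was 1.40 (1.003 to 1.925, exact p = 0.0378, unadjusted), and 1.29 (0.895 to 1.82) with 1 probe per gene.

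Several genes of the macrophage list were higher with ETS2 than with both other factors, and macrophages mixed into the ETS2 cultures could be a source of this signal. Of 19 listed genes with a probe, 7 were higher in ETS2 than in both, 0 were lower in both, and 8 were too dim to test, so the values do not decide. Adgre1, a macrophage marker, was at 12.11 with ETS2 against 12.60 with ERG (adjusted p = 0.0111). Lyz2 was at 13.16 with ETS2 against 10.17 with ERG and 11.42 with FLI1, and Tyrobp at 13.40 against 12.88 and 13.29. In all 3 groups 5 of the genes lay above the 75th percentile of the chip. None of the listed genes with a probe is on another list (0 of 19), which does not show that they are particular to macrophages. If the cells were selected for green fluorescence, this would remove macrophages that were not transduced but keep any that grew from transduced progenitors. An effect of ETS2 on the progenitors stays open, untested.

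Other divisions of the 8 ETS2 and FLI1 arrays into 4 and 4 were tried. For called probes 1 of the 35 divisions, the real one with 4683, reached that count, and the highest other gave 1. Each other division mixes arrays of both groups, so any real difference widens its spread and lowers its count. The arrays thus parted by group, but a chance difference between the cultures or embryos behind the groups is not excluded. For lists 3 of the 35 reached the real count of 9, and the highest other also gave 9, so chance cannot be excluded for the number of lists.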
